A study of Mus musculus with 39 samples.

How the data were processed

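Poly(dT)-selected RNA of mouse brain was sequenced in 39 libraries, 3 from each of 12 soman groups (3 doses at 4 days) and 3 from a saline group, per the labels' protocols. RNA was extracted with Trizol and converted to cDNA with a SmartScribe kit, per the labels' protocols. Reads were aligned with HISAT2, per the submitters' processing notes, which give no version and name the human build GRCh38 for these mouse samples, so no coordinates are used here. The deposited values are FPKM, in 1 table of 47561 genes by 39 libraries. Of these genes 1987 have an identifier made by the assembly, some of them with a gene symbol. The program that computed them is not named, and read counts are not used here. The steps between low values gave no whole reads back (1.84% of them at the commonest ratio), so that the depth per library and the precision it gives are unknown.

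Groups were taken from the labels. Genes at an FPKM of 1 or more in at least 3 libraries were tested (14701 genes), as log2(FPKM + 1), in 1 linear model of 13 groups with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). Each soman group, and the mean of all 12, was compared with saline, the 1/2 with the 1/10 LD50 dose over the 4 days, and day 14 with day 1 over the 3 doses. F-tests asked for any difference among days and for a dose effect that differs between days (interaction). P values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. Log2 changes on this scale understate those of genes near or below 1 FPKM.

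Of 40 gene lists written from general knowledge, 39 had at least 5 tested genes and were tested with camera of limma in 15 comparisons (585 tests adjusted together), at a preset correlation between genes of 0.01 and with the correlation estimated from the residuals. Members were counted adjusted over all genes and over the list alone. The tests, the lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from the 3 alternatives and the tests named below as added later.

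The named genes are the 12 largest rises and falls of the comparisons of all soman with saline, 1/2 with 1/10 LD50 and day 14 with day 1, the 4 largest of each group against saline, the 6 of smallest p in each F-test, and up to 4 members of smallest p of each called list. Each had a mean of 2 FPKM or more in a group. Apart from the list members, each also passed the test and had a gene symbol that is not that of a predicted locus. Ache, Bche and Chat were always to be named.

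The alternatives were a pseudocount of 0.1, no filter, median-ratio scaling, a model of only the groups compared, the replicate number as a block, the estimated correlation, and each library left out in turn. After the data were seen, 3 were added: removal of each library's trend on transcript length (lowess, span 0.5), leaving out the 2 libraries of highest mitochondrial share, and leaving out 7 libraries that lie between the other 2 of their group. Tests added then were those of a length trend alone and of a batch shared by a day for days 3 and 7, of a mixture for the 7 libraries, of doses within a day, the splits that move whole groups or keep libraries within days, and the group means of the meningeal list. Lengths came from GENCODE vM21 and were found for 14331 tested genes (97.48%). A library was held to lie between the others if, among genes of mean FPKM 5 or more and over 2-fold apart in the other 2, its share at positions 0.3 to 0.7 was above that of each of the 36 libraries of other groups. The meningeal list's mean log2 value was compared by a two-sided exact permutation test. The correlation of values with transcript length is not reported here. Splits, permutations and simulations were run in R. Library summaries, the search for libraries between others and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

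The code was tested on simulated data for 1/2 LD50 at day 3 against saline with 14701 genes. It called 43 of 50 genes changed 1.5-fold, 48 of 50 changed 2-fold, 50 of 50 changed 4-fold and 50 of 50 changed 8-fold, with 4 false calls among 14476 unchanged genes. The search for libraries between 2 others found 2 of 2 simulated mixtures and 1 of 37 other libraries. The simulated values varied independently from gene to gene, and groups did not differ apart from the genes changed. Real groups differ and their genes may vary together, so these figures check the code and are not error rates for the real libraries.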

Results

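RNA was sequenced from the brain of mice given soman under the skin, or saline. Soman is an organophosphate nerve agent that blocks acetylcholinesterase, the enzyme that breaks down acetylcholine at synapses. The doses were 1/10, 1/5 and 1/2 of the LD50, the dose that kills 50% of animals, and brains were taken at day 1, 3, 7 or 14. With a single saline group this gave 13 groups of 3 libraries and 39 libraries in all. The labels do not say how many animals each library was made from. The deposited table listed 47561 genes, and 9779 of them were at 0 in every library. Values were in FPKM, a measure scaled to transcript length and to the fragments mapped in each library. Read counts are not used here, and the depth of each library is unknown. The FPKM of a library summed to between 296322 and 342231 (median 312894), and 24769 to 29662 genes were above 0 (median 25844). No saline group was given for each day, and the labels do not say at which day the saline brains were taken or whether soman was given once or repeatedly. A difference from saline therefore holds any difference between collection days as well as that of the treatment.

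Of the 39 libraries, 8 stood apart from the rest in mitochondrial share or in lying between the other 2 of their group, and 1 of the 8 in both. Mitochondrial genes took 20.8% and 24.7% of the FPKM in replicates 2 and 3 of 1/10 LD50 at day 7, against 7.94% ± 2.19 in saline (SD, n = 3) and a median of 8.98% over all libraries. In 7 libraries the values lay between those of the other 2 libraries of their group. These were saline replicate 3, replicate 3 of each dose at day 1, replicate 2 of 1/10 LD50 at day 7, and replicate 3 of 1/10 LD50 and of 1/5 LD50 at day 14. Among genes over 2-fold apart in the other 2 libraries of the group, 47.6% to 77.3% took a position between 0.3 and 0.7 of the way from one to the other in these 7, against a median of 17.6% in the rest (highest 61.9%). In each of the 7 that share was above that of all 36 libraries of other groups set in its place. Counts of changed genes are given with and without such libraries. Some groups had more genes above 0, with 27920 ± 1289 at 1/5 and 28909 ± 909 at 1/2 LD50 at day 7 and 26651 ± 1679 at 1/10 LD50 at day 14, against 25871 ± 135 in saline.

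**Figure D1:**
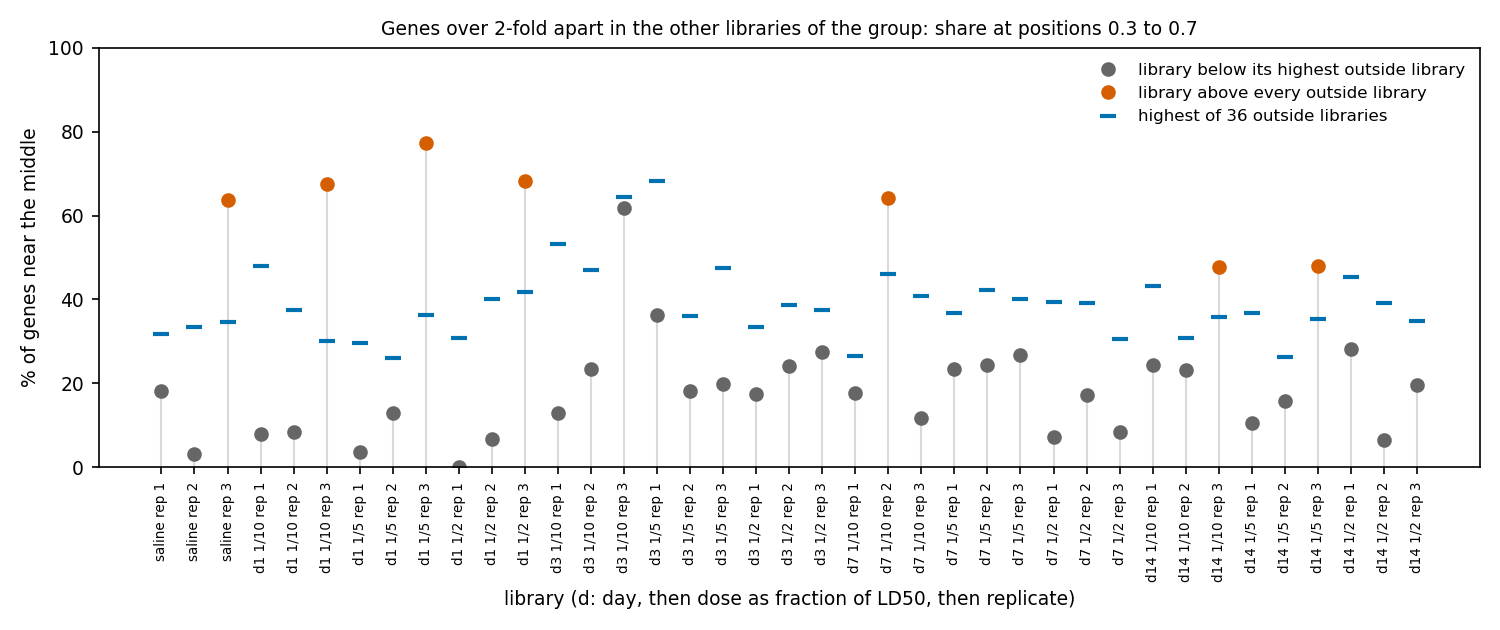
For each of the 39 libraries (x axis), the y axis gives the percentage of genes, among those over 2-fold apart in the other 2 libraries of its group, that lie at positions 0.3 to 0.7 between them (points), and the blue dash gives the highest of the 36 libraries of other groups set in its place. The 7 orange libraries, at 47.6% to 77.3%, lie above every outside library.

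The gene for the enzyme that soman blocks passed the test in none of 15 comparisons. Ache, which encodes acetylcholinesterase, stood at 32.2 ± 2.41 FPKM in saline (SD, n = 3) and 31.9 ± 4.55 over the 36 soman libraries, a log2 difference of -0.02 ± 0.10 (SE, limma adjusted p = 0.939). Below all saline libraries were 13 of the 36 and above all of them 8. The 13 include 3 of 3 at 1/10 LD50 (26.7 ± 2.00 FPKM, limma adjusted p = 0.484, 0.0586 before adjustment) and 3 of 3 at 1/5 LD50 (28.6 ± 0.639 FPKM, 0.988 and 0.225) at day 1. Bche, which encodes butyrylcholinesterase, a second soman target, stood at 0.925 ± 0.118 and 1.17 ± 0.222 FPKM, above all saline libraries in 24 of 36 (adjusted p = 0.373). Chat, which encodes the enzyme that makes acetylcholine, stood at 1.86 ± 0.303 and 1.86 ± 0.435 FPKM (adjusted p = 0.973, above all saline libraries in 11 of 36). None of these 3 genes passed the test at any dose and day against saline. Of 15 measured genes of cholinergic signalling, a list that holds these 3 with the acetylcholine receptors and transporters, the list test passed in none of 15 comparisons (lowest adjusted p = 0.279 at the preset correlation, 0.875 with an estimated correlation). The lists of other serine hydrolases (18 measured), dopaminergic and serotonergic neurons (14), the NRF2 antioxidant response (18), p53 and apoptosis (18), proliferation (6) and neurogenesis (14) also passed in none.

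At day 1, chaperones and other genes of the heat shock and unfolded protein response, which fold proteins in the endoplasmic reticulum and the cytosol, were lower than in saline. At 1/10 LD50, 13 of the 24 measured members fell and none rose (20 fell adjusted over the list alone), and the list test gave adjusted p = 0.00436 with an estimated correlation. Hspa5, the main chaperone of the endoplasmic reticulum, fell from 174.7 ± 6.69 to 75.9 ± 6.51 FPKM (SD, n = 3 each), a log2 change of -1.19 ± 0.13 (SE, adjusted p = 2.05e-06). Pdia4, a disulfide isomerase (log2 change -0.97 ± 0.10), Calr, a calcium-binding chaperone (-0.57 ± 0.06), and Manf, a secreted stress-response factor (-0.86 ± 0.10), fell as well. Each was below every saline library in 3 of 3. For 1/2 LD50 6 members fell (19 adjusted over the list alone), with adjusted p = 0.0112 with an estimated correlation. At 1/5 LD50 0 members passed over all genes in limma, where 843 genes of any kind were below 0.05 before adjustment, and 15 fell adjusted over the list alone. That list call (adjusted p = 0.0317 with an estimated correlation) was lost without saline replicate 1 (0.0671), saline replicate 3 (0.0531) or replicate 1 of the dose (0.211), and without the 7 libraries (0.124). The calls at 1/10 and 1/2 LD50 held without each of their 6 libraries (highest adjusted p 0.00605 and 0.0369) and without the 7 libraries (0.0118 and 0.0376).

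Immediate early genes, which neurons switch on after firing, were also lower at day 1. At 1/10 LD50 6 of 29 measured members fell and none rose (14 fell adjusted over the list alone). Arc, a regulator of synaptic receptors, went from 39.9 ± 2.85 to 12.6 ± 2.15 FPKM (SD, n = 3 each). The log2 change of Arc was -1.60 ± 0.22 (SE, adjusted p = 0.000114, 3 of 3 libraries below all saline). Fos, a transcription factor subunit, fell by 1.32 ± 0.23 on the log2 scale and Dusp1, a phosphatase of MAP kinases, by 0.96 ± 0.17. Adjusted p for the list was 0.0456 with an estimated correlation, and the call was lost without saline replicate 1 (0.0685), saline replicate 2 (0.0767), or replicate 1 (0.12) or 3 (0.0884) of the dose, and without the 7 libraries (0.113). At 1/2 LD50 2 members fell (16 adjusted over the list alone, adjusted p = 0.0408 with an estimated correlation). That call was lost without saline replicate 1 (0.0781) or 2 (0.0686) or replicate 1 (0.094) or 3 (0.051) of the dose, and without the 7 (0.0593). At 1/5 LD50 Npas4, a transcription factor of active neurons, fell by 1.18 ± 0.20, while 5 members fell adjusted over the list alone and the list test was lost with an estimated correlation (adjusted p = 0.132). Interferon response genes, which cells induce against viruses, fell in 2, 0 and 0 of 22 members from the lowest to the highest dose, with 16, 14 and 11 adjusted over the list alone. Their list call was lost at each dose with an estimated correlation (adjusted p = 0.155, 0.132 and 0.302). Rises at 1/10 LD50 included Rbm3, an RNA-binding protein induced by cold (21.3 ± 3.13 to 39.8 ± 7.25 FPKM, log2 change 0.87 ± 0.14, adjusted p = 0.00119). Alkbh3, a demethylase of alkylated nucleic acids, rose too (3.8 ± 0.333 to 8.18 ± 1.60 FPKM, 0.92 ± 0.16, adjusted p = 0.00239). Both were above every saline library in 3 of 3. Rpl30, a ribosomal protein gene with near-identical copies in the genome and so of uncertain level, fell from 64.5 ± 6.81 to 8.32 ± 1.54 FPKM at 1/2 LD50.

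Across all genes at day 1, 51 changed at 1/10 LD50 (10 rose, 41 fell), 2 at 1/5 LD50 (Npas4 and Dhx8, a splicing helicase, both of which fell) and 17 at 1/2 LD50 (4 rose, 13 fell). With only the groups compared in the model the counts were 122, 27 and 30. The 2 at 1/5 LD50 were lost without saline replicate 1 or 3 or replicate 1 or 3 of the dose (adjusted p up to 0.214). Leaving out 1 library gave 28 without saline replicate 3, 28 without replicate 2 and 32 without replicate 3 of 1/10 LD50. For 1/5 LD50 it gave 4 without saline replicate 1 or 2, 0 without saline replicate 3 (682 below 0.05 before adjustment) or replicate 3 of the dose (612), 1 without its replicate 1 and 6 without its replicate 2. For 1/2 LD50 it gave 5, 8 and 6 without saline replicates 1, 2 and 3, and 3 without replicate 1 or 3 of the dose. Without the 7 libraries between the others of their group the counts were 9, 0 (406 below 0.05 before adjustment in limma) and 1. Hspa5, Pdia4, Calr, Manf and Arc at 1/10 LD50 and Rpl30 at 1/2 LD50 still passed while Fos, Dusp1, Rbm3 and Alkbh3 did not (adjusted p = 0.164, 0.164, 0.0946 and 0.172). Their log2 changes with these fewer libraries were -1.37, -1.01, 0.93 and 0.89. Genes of meningeal fibroblasts, the collagen-making cells of the membranes around the brain, had median log2 changes of -0.09, -0.26 and 0.03 at day 1 from the lowest to the highest dose (adjusted p = 0.901, 0.125 and 0.974 with an estimated correlation).

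**Figure D2:**
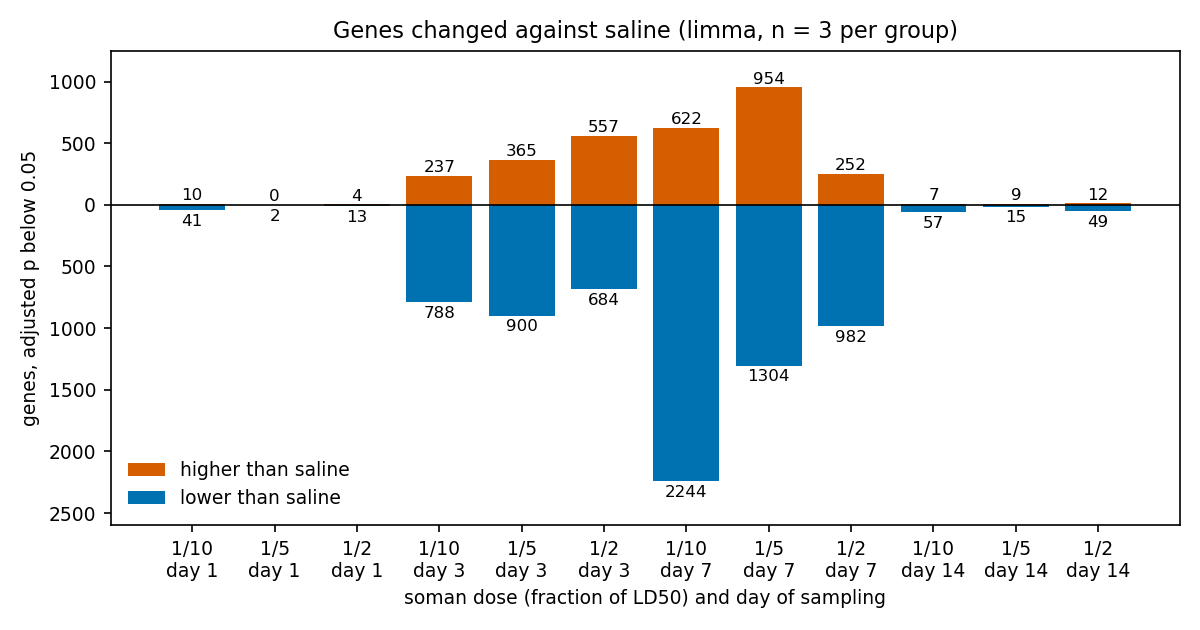
Bars give the number of genes higher (orange, upward) and lower (blue, downward) than saline at an adjusted p below 0.05 in limma for each dose (fraction of the LD50) and day, with 3 libraries per group. Counts run from 2 at 1/5 LD50 at day 1 to 2866 at 1/10 LD50 at day 7, and at each of the 12 comparisons more genes fell than rose in this fit of all 13 groups, which does not hold at 5 of the 12 with only the groups compared in the model.

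At day 3 immediate early genes were again below saline, and genes of meningeal fibroblasts were lower too. Of the 29 immediate early genes 15, 16 and 9 fell from the lowest to the highest dose and none rose (19, 19 and 13 fell adjusted over the list alone). Fos fell from 11.4 ± 1.14 FPKM in saline to 3.26 ± 1.16, 2.67 ± 2.10 and 4.27 ± 0.235 (SD, n = 3 each). Its log2 changes were -1.58 ± 0.23, -1.90 ± 0.23 and -1.23 ± 0.23 (SE, adjusted p = 0.000187, 3.61e-05 and 0.00173, 3 of 3 libraries below all saline at each dose). Arc fell by 1.51 ± 0.22, 1.66 ± 0.22 and 1.15 ± 0.22 and Dusp4, a MAP kinase phosphatase, by 0.72 ± 0.11, 0.73 ± 0.11 and 0.60 ± 0.11. The list gave adjusted p = 0.124, 0.0456 and 0.132 with an estimated correlation. Its call at 1/5 LD50 was lost without saline replicate 1 (0.0671) or 2 (0.076) or replicate 1 (0.0622) or 2 (0.0525) of the dose, and without the 7 libraries (0.0572). Of 17 meningeal fibroblast markers 7, 12 and 11 fell (10, 12 and 13 adjusted over the list alone), with adjusted p = 0.176, 0.124 and 0.0172 with an estimated correlation. The call at 1/2 LD50 held without each of the 6 libraries (highest adjusted p 0.0406) and without the 7 libraries (0.0187). There Col3a1, a fibrillar collagen, fell from 5.91 ± 0.557 to 2.90 ± 0.356 FPKM (log2 change -0.82 ± 0.13, adjusted p = 0.000444). Slc47a1, a transporter, fell from 2.56 ± 0.334 to 0.618 ± 0.0575 FPKM (-1.14 ± 0.17, adjusted p = 0.000226), and both were below all saline in 3 of 3 libraries. Chaperones of the heat shock and unfolded protein response fell in 9, 12 and 12 of 24 members (10, 14 and 13 adjusted over the list alone, with 1 risen at 1/2 LD50). Hspa5 fell by log2 changes of -0.72 ± 0.13, -0.96 ± 0.13 and -0.92 ± 0.13. Their list call was lost at each dose (adjusted p = 0.366, 0.192 and 0.124 with an estimated correlation).

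Voltage-gated ion channels, long transcripts that carry neuronal currents, fell in 7, 8 and 6 of 21 members at day 3 (10, 10 and 7 adjusted over the list alone, adjusted p = 0.253, 0.225 and 0.155 with an estimated correlation). Scn1a, a sodium channel, fell from 26.2 ± 1.11 to 18.7 ± 0.312, 17.6 ± 2.25 and 17.4 ± 1.5 FPKM (SD, n = 3 each). Its log2 changes were -0.46 ± 0.10, -0.55 ± 0.10 and -0.57 ± 0.10 (SE). Cytosolic ribosomal proteins, encoded by short transcripts, rose in 2, 6 and 9 of 32 members (15, 12 and 19 adjusted over the list alone, adjusted p = 0.507, 0.572 and 0.551 with an estimated correlation). The genes that rose had a median transcript length of 1982, 1883 and 2143 bases and those that fell one of 6694, 6685 and 7052, against 3274 for all tested genes. With each library's trend on transcript length removed, Scn1a gave adjusted p = 0.0585, 0.0133 and 0.00571, and Fos, Arc and Hspa5 still passed at each dose. Antigen presentation genes, which show peptides to T cells, rose in 4 of 13 members at 1/2 LD50 (10 adjusted over the list alone, adjusted p = 0.551 with an estimated correlation). Among them Tap1, a peptide transporter, was lost without replicate 1 of the dose (adjusted p = 0.171). Gbp4 and Gbp5, interferon-induced GTPases, were lost without that library (0.213 and 0.179), saline replicate 1 (0.0576 and 0.0592) or saline replicate 3 (0.0603 and 0.0517), and Gbp4 stood at 5.97 ± 6.99 FPKM. Choroid plexus markers, of the tissue that makes cerebrospinal fluid, fell in 6, 3 and 3 of 16 members (13, 12 and 11 adjusted over the list alone, adjusted p = 0.58, 0.637 and 0.638 with an estimated correlation). Rbm3 rose at 1/10 and 1/5 LD50 by 1.08 ± 0.14 and 0.96 ± 0.14 on the log2 scale (adjusted p = 0.000113 and 0.000132, 3 of 3 libraries above all saline).

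In all, 1025 genes changed at 1/10 LD50 at day 3 (237 rose, 788 fell, or 73 and 141 with only the groups compared), 1265 at 1/5 LD50 (365 rose, 900 fell, or 177 and 173 with only the groups compared) and 1241 at 1/2 LD50 (557 rose, 684 fell, or 454 and 1034 with median-ratio scaling and 527 and 453 with only the groups compared). Without saline replicates 1, 2 and 3 the counts were 617, 654 and 467 at 1/10 LD50, 672, 796 and 591 at 1/5 LD50 and 649, 765 and 487 at 1/2 LD50. Without 1 soman library they were 349 (replicate 2 of 1/10 LD50), 578 and 453 (replicates 1 and 2 of 1/5 LD50) and 297 (replicate 1 of 1/2 LD50). Without the 7 libraries they were 144, 203 and 140, and with the length trend removed 461, 589 and 549.

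At day 7 meningeal fibroblast markers were below saline, and 11 of 29 immediate early genes were below it at 1/10 LD50, the group with the 2 libraries of high mitochondrial share. Of 17 meningeal markers 13 fell at 1/5 LD50 (15 adjusted over the list alone) and 13 at 1/2 LD50 (17 adjusted over the list alone). The list gave adjusted p = 0.0112 and 0.00745 with an estimated correlation. Col3a1 fell from 5.91 ± 0.557 to 1.96 ± 0.278 and 2.45 ± 0.588 FPKM (SD, n = 3 each). Its log2 changes were -1.22 ± 0.13 and -1.01 ± 0.13 (SE, adjusted p = 1.03e-06 and 4.62e-05, 3 of 3 libraries below all saline). Igf2, a growth factor made by the meninges, fell by 1.00 ± 0.13 and 1.12 ± 0.13, and Slc13a4, a sulfate transporter, by 1.02 ± 0.12 and 0.95 ± 0.12. Both list calls held without each of the 6 libraries (highest adjusted p 0.0209 and 0.0183) and without the 7 libraries (0.0118 at both doses). At 1/10 LD50 10 of the 17 fell and 1 rose (11 fell and 1 rose adjusted over the list alone), with adjusted p = 0.302 with an estimated correlation. Among the immediate early genes 11 of 29 fell at 1/10 LD50, where Arc stood at 12.0 ± 3.64 FPKM against 39.9 ± 2.85 in saline (log2 change -1.69 ± 0.22, adjusted p = 0.00013). At 1/5 LD50 6 rose, among them Fosb, which encodes a transcription factor (1.17 ± 0.137 to 2.23 ± 0.282 FPKM, 0.58 ± 0.12, adjusted p = 0.00175). At 1/2 LD50 6 rose and 1 fell. Adjusted over the list alone 12 fell at 1/10 LD50, 6 rose at 1/5 LD50, and 9 rose and 2 fell at 1/2 LD50. The list was lost at all 3 doses with an estimated correlation (adjusted p = 0.738, 0.719 and 0.675).

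Voltage-gated ion channels fell at day 7 in 8, 13 and 9 of 21 members from the lowest to the highest dose (8, 14 and 12 adjusted over the list alone, with 1 risen at 1/5 LD50; adjusted p = 0.678, 0.103 and 0.255 with an estimated correlation). Scn1a fell to 14.2 ± 0.432 FPKM at 1/5 LD50 (log2 change -0.84 ± 0.10, adjusted p = 3.25e-06, 3 of 3 libraries). Ribosomal protein genes rose in 19 of 32 members at 1/5 LD50 and 9 at 1/2 LD50 (28 and 15 adjusted over the list alone, adjusted p = 0.302 and 0.415 with an estimated correlation). Rpl38, one of them, rose from 98.1 ± 6.83 to 177.4 ± 8.01 FPKM at 1/5 LD50 (0.85 ± 0.13, adjusted p = 5.51e-05). Nuclear-encoded subunits of the respiratory chain rose in 12 of 30 members at 1/5 LD50 (18 adjusted over the list alone, adjusted p = 0.738 with an estimated correlation). At 1/5 LD50 the genes that rose had a median transcript length of 1751.5 bases and those that fell one of 6695, and with the length trend removed Scn1a and Rpl38 passed (log2 changes -0.62 and 0.59, adjusted p = 5.08e-05 and 0.000871). The rises of the respiratory chain genes Cox6a1, Cox4i1 and Cox5b did not (0.16, 0.13 and 0.22, adjusted p = 0.301, 0.165 and 0.106), against 0.41 ± 0.10, 0.37 ± 0.09 and 0.45 ± 0.11 before. That of Ndufb7, of the same list, still passed with the trend removed (0.50, limma adjusted p = 0.00114). Lnpep, an aminopeptidase, fell from 14.5 ± 1.23 to 5.05 ± 0.659 FPKM at 1/5 LD50 (-1.37 ± 0.14, adjusted p = 8.44e-07, 3 of 3 libraries), the smallest p among the named falls of that group. Hspa5 and Pdia4 fell at 1/2 LD50 by 0.82 ± 0.13 and 0.72 ± 0.10, among 8 of 24 fallen members of the heat shock and unfolded protein response (12 adjusted over the list alone, adjusted p = 0.368 with an estimated correlation). Choroid plexus markers fell in 6, 7 and 8 of 16 members (8, 10 and 13 adjusted over the list alone, adjusted p = 0.901, 0.637 and 0.507 with an estimated correlation). Markers of the cerebellum fell in 2 and 3 of 15 members at 1/5 and 1/2 LD50 (2 and 13 adjusted over the list alone, adjusted p = 0.89 and 0.678 with an estimated correlation). Among them was Itpr1, a calcium channel of Purkinje cells, at 154.8 ± 11 FPKM in saline and 76.5 ± 10.4 and 73.2 ± 15.5 at these doses. Markers of the striatum lay the other way, with 4 and 1 of 16 risen at these doses (4 and 1 adjusted over the list alone, adjusted p = 0.901 and 0.738 with an estimated correlation). At the preset correlation striatum markers were called higher in 10 of the 15 comparisons and cerebellum markers lower in 6, and with an estimated correlation in none (lowest adjusted p = 0.373 and 0.678).

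At 1/10 LD50 at day 7, all 13 measured genes of the mitochondrial genome rose (13 adjusted over the list alone, adjusted p = 0.124 with an estimated correlation). ATP6 rose from 2319 ± 818 to 6899 ± 3000 FPKM (SD, n = 3 each). Mitochondrial transfer RNAs had the largest rises there, with TrnR at 4.96 ± 1.84 FPKM in saline and 21.9 ± 7.29 after soman (log2 change 1.93 ± 0.31). Without the 2 libraries of highest mitochondrial share, which leaves 1 library whose spread is taken to be that of the other groups, 4 genes changed in this group in place of 2866. None of ATP6, TrnR, Arc and Col3a1 passed there (log2 changes 0.67, 1.33, -1.26 and -0.52, adjusted p = 0.478, 0.248, 0.136 and 0.253).

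The counts at day 7 were 2866 at 1/10 LD50 (622 rose, 2244 fell, or 1079 and 1297 with median-ratio scaling and 3 and 2 with only the groups compared), 2258 at 1/5 LD50 (954 rose, 1304 fell, or 1462 and 1370 with only the groups compared) and 1234 at 1/2 LD50 (252 rose, 982 fell, or 144 and 412 with only the groups compared). The count for 1/10 LD50 was 1506 without saline replicate 3, and 5304, 1732 and 668 without replicates 1, 2 and 3 of the dose. For 1/5 LD50 it was 1246 without saline replicate 3 and 1131 without replicate 3 of the dose. For 1/2 LD50 it was 740 and 515 without saline replicates 1 and 3 and 277 without replicate 1 of the dose. Without the 7 libraries the counts were 69, 756 and 196, and with the length trend removed 938 genes changed at 1/5 LD50 and 537 at 1/2 LD50.

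By day 14 few genes differed from saline, and the immediate early genes lay above it. Of the 29, 4, 2 and 3 rose from the lowest to the highest dose and none fell (10, 13 and 13 rose adjusted over the list alone), with adjusted p = 0.0456, 0.0684 and 0.0444 with an estimated correlation. At 1/2 LD50 Fosb rose from 1.17 ± 0.137 to 2.61 ± 0.308 FPKM (SD, n = 3 each), a log2 change of 0.73 ± 0.12 (SE, adjusted p = 0.0054, 3 of 3 libraries above all saline). The list call at 1/10 LD50 was lost without saline replicate 1 (0.0671), 2 (0.0613) or 3 (0.114) or replicate 1 (0.152) or 3 (0.0782) of the dose, and without the 7 libraries (0.162). The call at 1/2 LD50 was lost without saline replicate 1 (0.0526), 2 (0.0613) or 3 (0.114) or replicate 1 (0.104) or 2 (0.11) of the dose, and without the 7 (0.13). Meningeal fibroblast markers were below saline, with 7, 2 and 6 of 17 fallen (11, 8 and 14 adjusted over the list alone) and adjusted p = 0.0168, 0.0408 and 0.00507 with an estimated correlation. At 1/2 LD50 that call held without each of the 6 libraries (highest adjusted p 0.0165). Col3a1 fell there from 5.91 ± 0.557 to 2.97 ± 0.266 FPKM (-0.80 ± 0.13, adjusted p = 0.0054, 3 of 3 libraries). At 1/10 LD50 it was lost without saline replicate 1 (0.0526) or replicate 3 of the dose (0.0503), and at 1/5 LD50 without saline replicate 1 (0.0781) or replicate 2 of the dose (0.064). Glucocorticoid response genes rose in 0 of 17 members at 1/2 LD50 over all genes in limma, where 1313 genes of any kind were below 0.05 before adjustment, and in 9 adjusted over the list alone. Their call (adjusted p = 0.0456 with an estimated correlation) was lost without saline replicate 1 (0.0788), 2 (0.0613) or 3 (0.0949) or replicate 1 (0.159) or 2 (0.0565) of the dose, without the 7 libraries (0.157) and without the 2 of highest mitochondrial share (0.0755). Interferon response genes fell in 1 of 22 members at each dose (13, 12 and 13 adjusted over the list alone), and their call was lost with an estimated correlation (adjusted p = 0.25, 0.192 and 0.186). Red blood cell genes fell in 4 of 8 members at 1/5 LD50 (5 adjusted over the list alone, adjusted p = 0.0231 with an estimated correlation, or 0.0648 without saline replicate 2 and 0.0568 without the 7 libraries). They included the haemoglobin gene Hba-a1, from 282.0 ± 16.7 to 83.5 ± 25.7 FPKM, whose level is uncertain because of a near-identical copy. Its call was lost without saline replicate 1 or 3 or replicate 2 or 3 of the dose (adjusted p up to 0.117).

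The counts at day 14 were 64 at 1/10 LD50 (7 rose, 57 fell), 24 at 1/5 LD50 (9 rose, 15 fell, or 41 and 30 with only the groups compared, 8 and 7 with no filter, and 3 and 0 without replicate 3 of the dose) and 61 at 1/2 LD50 (12 rose, 49 fell, or 13 and 19 with only the groups compared). For 1/10 LD50 they were 38, 26 and 23 without saline replicates 1, 2 and 3, and 35, 9 and 32 without replicates 1, 2 and 3 of the dose. For 1/5 LD50 they were 13, 10 and 0 (1117 below 0.05 before adjustment in limma) without these saline replicates, and 10, 0 (1185) and 3 without those of the dose. For 1/2 LD50 they were 19, 13 and 19, and 10, 34 and 18. Without the 7 libraries limma called 0 genes at each dose, with 1186, 646 and 965 below 0.05 before adjustment. The meningeal list was still called at 1/2 LD50 (adjusted p = 0.0118 with an estimated correlation), though not at 1/10 (0.0568) or 1/5 LD50 (0.0548).

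**Figure D3:**
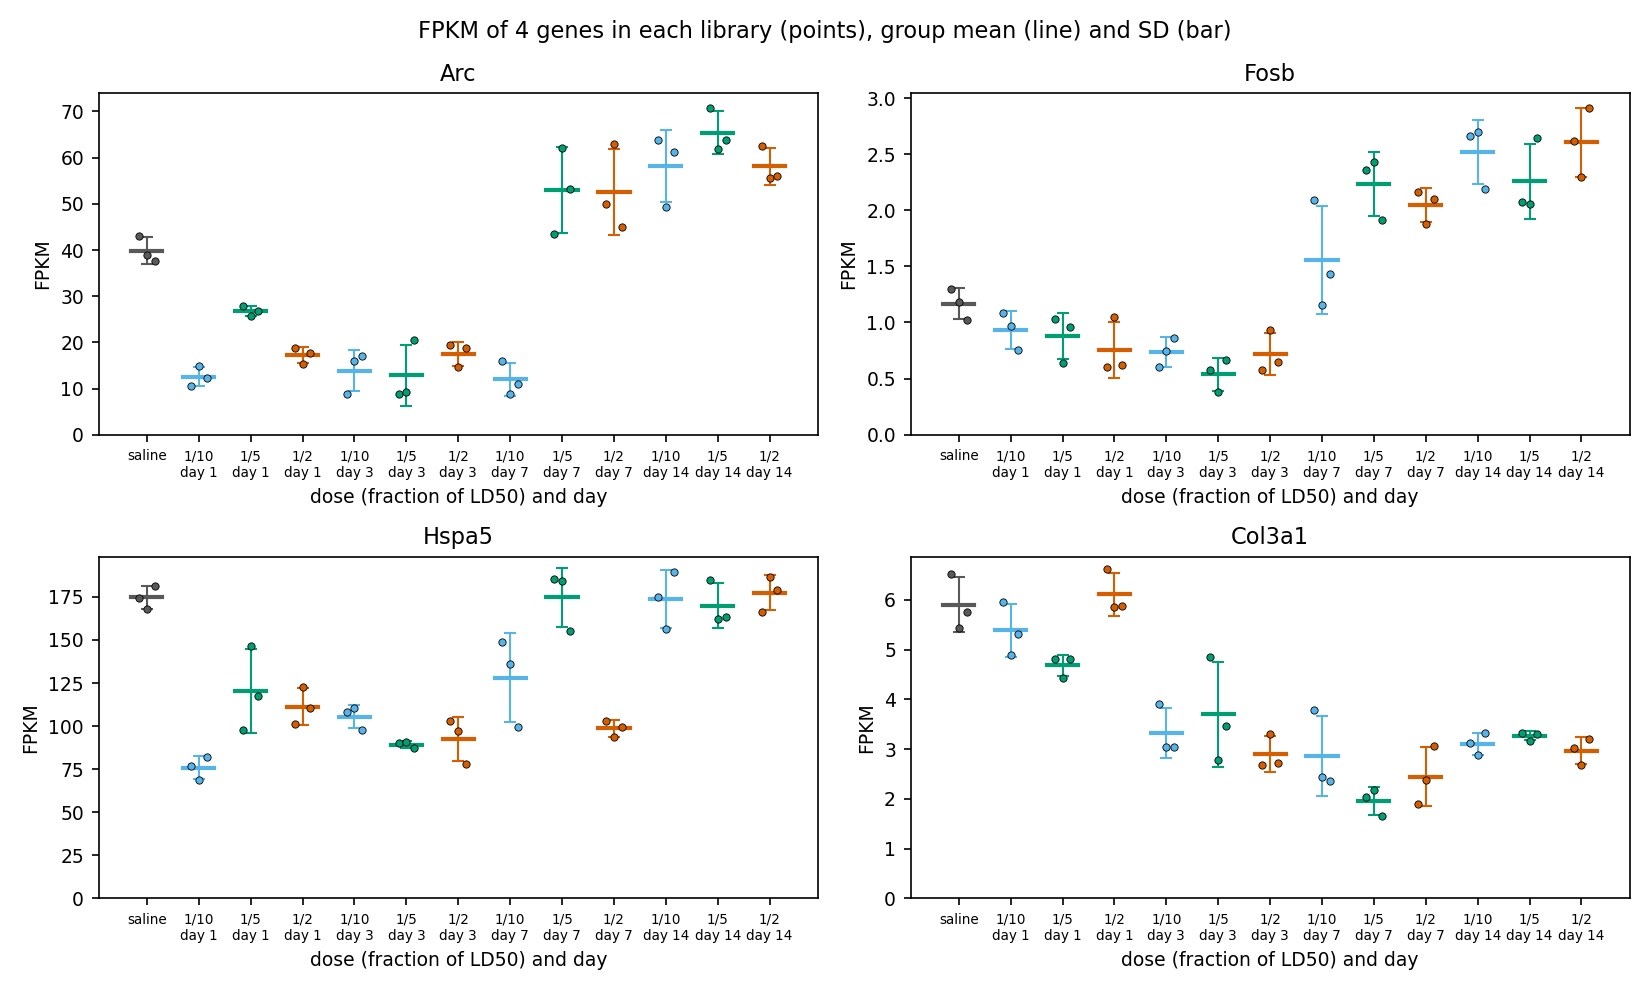
FPKM of Arc, Fosb, Hspa5 and Col3a1 (y axes) in each of the 39 libraries (points) by dose (fraction of the LD50) and day, with the group mean (line) and SD (bar) of 3 libraries. Arc lies at 39.9 ± 2.85 in saline, at 12.6 ± 2.15 to 26.7 ± 1.04 at day 1 and at 58.1 ± 3.92 to 65.4 ± 4.65 at day 14.

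Over the mean of all 12 soman groups, meningeal fibroblast markers stood below saline. Of the 17, 10 fell and none rose (13 fell adjusted over the list alone), with a median log2 change of -0.39 and adjusted p = 0.0112 with an estimated correlation. The call held without each of the 39 libraries (highest adjusted p 0.0492) and without the 7 libraries (0.0145). Their mean log2 value was 2.77 ± 0.105 in saline (SD, n = 3) and 2.40 ± 0.206 in soman (n = 36), below the lowest saline library in 31 of 36 (two-sided exact permutation test over 9139 splits, which treats libraries as independent, p = 0.00295). By group, saline was second highest of 13, below 1/2 LD50 at day 1 (2.776 ± 0.034 against 2.773 ± 0.105). Next came 1/10 (2.687 ± 0.042) and 1/5 LD50 (2.538 ± 0.036) at day 1, and all groups of days 3 to 14 lay lower (2.46 ± 0.044 at most). The soman libraries not below the lowest saline one were all of day 1. Col3a1 went from 5.91 ± 0.557 to 3.56 ± 1.27 FPKM (log2 change -0.65 ± 0.10, adjusted p = 0.00175, below all saline libraries in 32 of 36, lost without replicate 3 of every group at 0.127). Igf2 fell by 0.58 ± 0.10 (33 of 36) and Slc13a4 by 0.53 ± 0.09 (34 of 36). Rbm3 rose from 21.3 ± 3.13 to 34.3 ± 7.62 FPKM (0.64 ± 0.10, adjusted p = 0.00231, above all saline libraries in 35 of 36). Its call was lost without saline replicate 1 or replicate 3 of every group (adjusted p up to 0.127). Other rises included Ccl27b, a chemokine, and Gas5, a host gene of small nucleolar RNAs, and other falls included Itpr1 (below all saline libraries in 32 of 36), Npas4 (below in 24, above in 6) and Fos (below in 21, above in 11). The mean of Fos hides opposite directions by day, as it stood at 14.4 ± 1.58 FPKM at day 14 (n = 9) against 11.4 ± 1.14 in saline. In all 378 genes changed (61 rose, 317 fell, and 2453 were below 0.05 before adjustment). The call of each of the 12 largest rises and 12 largest falls was lost in at least 1 of 6 leave-outs. The count was 45, 29 and 7 without saline replicates 1, 2 and 3, and 36, 20 and 0 (1564 below 0.05 before adjustment in limma) without replicates 1, 2 and 3 of every group. It was 1 without the 7 libraries, 671 without the 2 of highest mitochondrial share, 85 with the length trend removed and 0 in limma with soman pooled as 1 group against saline (1184 below 0.05 before adjustment).

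Days were compared without the saline group, by setting the 9 libraries of day 14 against the 9 of day 1. Immediate early genes were higher at day 14, with 27 of 29 risen and none fallen (27 adjusted over the list alone, adjusted p = 0.00292 with an estimated correlation). Arc rose from 18.9 ± 6.41 to 60.6 ± 6.15 FPKM (SD, n = 9 each), a log2 change of 1.69 ± 0.13 (SE, adjusted p = 3.17e-10). Fos, Nr4a1, a nuclear receptor, Junb, a partner of Fos, and Fosb rose by 1.41 ± 0.14, 1.39 ± 0.13, 1.10 ± 0.10 and 0.90 ± 0.07. All 5 were higher in 9 of 9 libraries of day 14 than in every library of day 1. The heat shock and unfolded protein response rose in 23 of 24 members (23 adjusted over the list alone, adjusted p = 0.00466 with an estimated correlation). Among them were Pdia4 (15.8 ± 3.16 to 26.3 ± 1.89 FPKM, 0.71 ± 0.06, adjusted p = 2.43e-09), Manf (0.70 ± 0.06) and Hsph1, a cytosolic chaperone (0.52 ± 0.05), in 9 of 9 libraries each. Both list calls held without each of the 18 libraries (highest adjusted p 0.00523 and 0.008) and without the 7 libraries (0.00813 and 0.0118). Meningeal fibroblast markers fell in 10 of 17 members (13 adjusted over the list alone, adjusted p = 0.0458 with an estimated correlation), a call that was lost without any of 14 of the 18 libraries (adjusted p up to 0.0774) and without the 7 (0.0805). The largest falls among the named genes were those of the haemoglobin genes Hba-a2, Hbb-bt, Hba-a1 and Hbb-bs. Their log2 changes were -1.34 ± 0.32, -1.33 ± 0.23, -1.29 ± 0.19 and -1.29 ± 0.22. All passed in limma (highest adjusted p 0.00461), though Hba-a2 did not without the 7 libraries (0.0761). The red blood cell list did not pass here with an estimated correlation, and a difference in blood content was not tested. Eln, the gene of elastin, fell from 8.98 ± 1.69 to 3.91 ± 0.885 FPKM (-1.03 ± 0.10, adjusted p = 2.14e-08, 9 of 9 libraries), Opalin, a myelin protein, by 0.62 ± 0.08 and Fn1, fibronectin, by 0.59 ± 0.08.

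Between day 14 and day 1, 2197 genes changed (1069 rose and 1128 fell). More rose than fell with median-ratio scaling (1420 and 1137), with only the groups compared (1471 and 1455), without the 7 libraries (352 and 333) and without any of 5 single libraries. All 12 of the largest rises and 11 of the 12 largest falls passed without each of the 18 libraries, the exception being Rps2, a gene with near-identical copies (adjusted p up to 0.0793). Any difference among the 4 days was found for 7277 of 14701 genes. The smallest p were those of Nr4a3 (adjusted p = 1.32e-12), P4ha1, a collagen hydroxylase, and Fosb (3.30e-12 each), Arc (5.69e-12), and Fos and Dusp4 (7.76e-11 each). Nr4a3 stood at 4.96 ± 0.311 FPKM in saline, at 2.63 ± 0.267 to 3.24 ± 0.667 at day 3 and at 6.29 ± 0.481 to 7.50 ± 0.403 at day 14. The count among the 4 days was 3693 without replicate 2 and 4343 without replicate 3 of every group, and without the 7 libraries 4409 genes differed among days and 685 between day 14 and day 1.

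**Figure D4:**
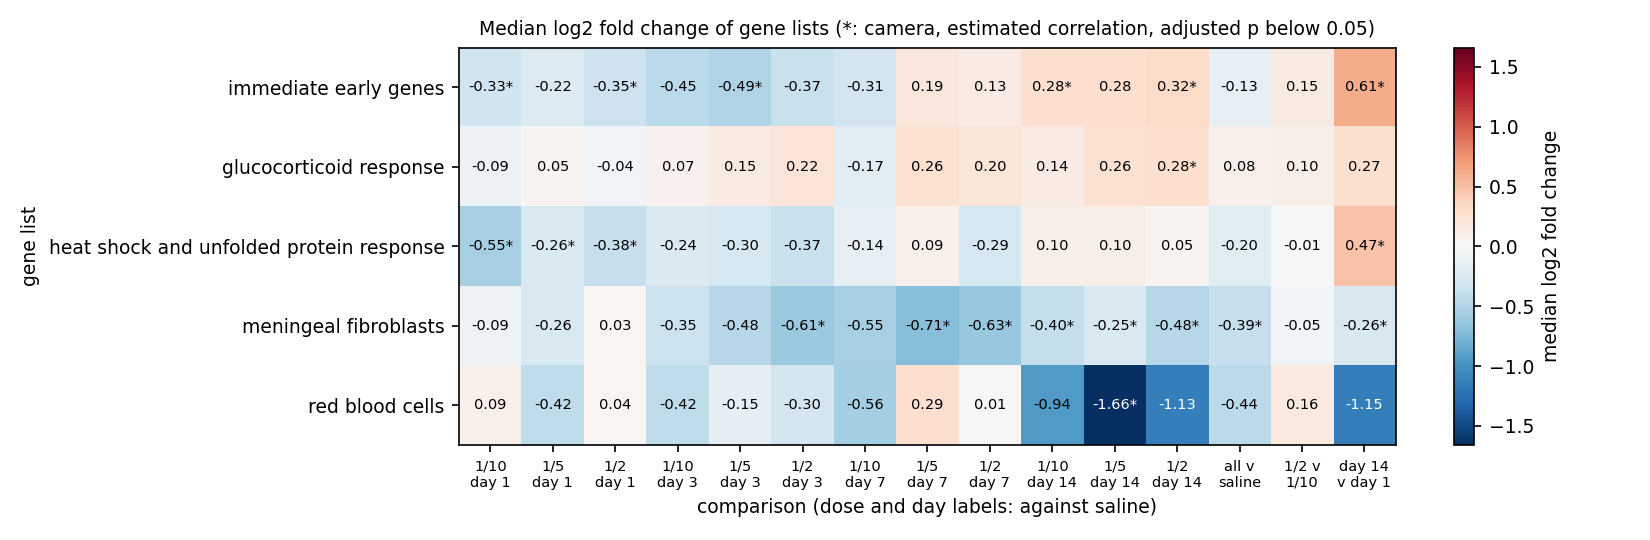
Median log2 change (color and number) of the 5 gene lists (y axis) that passed camera with an estimated correlation in at least 1 of 15 comparisons (x axis), with an asterisk where the adjusted p was below 0.05. Immediate early genes run from -0.49 at 1/5 LD50 at day 3 to 0.61 between day 14 and day 1, and meningeal fibroblast markers reach -0.71 at 1/5 LD50 at day 7.

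Doses differed for few genes when averaged over days, and for many within day 7. Between 1/2 and 1/10 LD50 6 genes changed (5 rose, 1 fell, and 2918 were below 0.05 before adjustment). Arc was higher at 1/2 LD50 (36.4 ± 20.4 against 24.2 ± 20.9 FPKM, SD, n = 12 each), with a log2 difference of 0.72 ± 0.11 (SE, adjusted p = 0.00329), though no library of 1/2 LD50 lay above all of 1/10 LD50. It did not pass without the 2 libraries of highest mitochondrial share (log2 difference 0.61, adjusted p = 0.0658) or without the 7 libraries (0.68, 0.201). Rpl30 was lower (-0.93 ± 0.15), of uncertain level because of its copies. Junb (0.47 ± 0.09), Hacd1, a fatty acid dehydratase (0.25 ± 0.05), and Tut1, a uridylyltransferase (0.22 ± 0.04), rose and were each lost without 1 of 12, 12 and 7 of the 24 libraries (adjusted p up to 0.101, 0.1 and 0.0597). The sixth gene is a predicted locus. Leaving out 1 library gave 3 genes for replicate 1 at day 1, replicate 1 at day 3, replicate 3 at day 7 and replicate 2 at day 14 of 1/10 LD50. It gave 3 as well for replicate 3 at day 1 and replicate 1 at day 7 of 1/2 LD50. The count was 13 without replicate 2 of 1/2 LD50 at day 1 or replicate 3 of 1/10 LD50 at day 3, 15 without replicate 3 of 1/2 LD50 at day 3, 28 without replicate 3 of 1/10 LD50 at day 14 and 2555 without replicate 1 of 1/10 LD50 at day 7. Without the 2 libraries of highest mitochondrial share, without the 7 libraries or with the length trend removed it was 2 each time. Within day 7, in a comparison chosen after the data were seen, 2597 genes differed between 1/2 and 1/10 LD50, 4056 between 1/5 and 1/10 and 17 between 1/2 and 1/5. Without the 2 libraries of highest mitochondrial share, which leaves 1 library at 1/10 LD50, these counts were 6, 8 and 23, and without the 7 libraries 282, 2159 and 9. Over the 4 days, 2 of the 29 immediate early genes were higher at 1/2 than at 1/10 LD50 (16 adjusted over the list alone, adjusted p = 0.351 with an estimated correlation). Meningeal fibroblast markers fell in 0 of 17 in limma (3 adjusted over the list alone, adjusted p = 0.25 with an estimated correlation).

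The 3 doses shared many of their changes against the shared saline group at days 3 and 7, few at day 14 and none at day 1. At day 3 94 genes rose and 470 fell at all 3 doses, and at day 7 47 rose and 387 fell, against 2 and 6 at day 14 and 0 and 0 at day 1. The correlation of log2 changes between doses, across genes, which are not independent replicates, averaged 0.80 at day 3, 0.49 at day 1, 0.52 at day 7 and 0.60 at day 14. Because all doses share 3 saline libraries, simulations with no change at all gave a mean of 0.49 to 0.50 and at most 0.77, a range that holds the values of days 1, 7 and 14. The covariance, which also grows with the size of changes, was above every simulation at day 3 (0.0415 against 0.0247 at most) and day 7 (0.0312 against 0.0278). It was not at day 1 (0.0147 against 0.0231) or day 14 (0.0184 against 0.0253). In 100 simulations per day no gene passed at all 3 doses. As no group differed in them, genes would seldom pass at even 1 dose, so this cannot show where the shared changes come from. Of 39 gene lists tested in 15 comparisons, 32 passed in at least 1 at the preset correlation and 5 with an estimated correlation, and 9 of the 20 calls with an estimated correlation held without the 7 libraries. Those called at the preset correlation alone include reactive astrocytes (lower in 6 comparisons), and inflammatory cytokines and mediators (higher in 1), with lowest adjusted p = 0.368 and 0.638 with an estimated correlation. The 191 calls at the preset correlation stand beside a median of 173 and a highest of 267 after random regrouping of the libraries, and the 20 calls with an estimated correlation beside a highest of 9. With whole groups exchanged in place of libraries, the highest were 234 and 21.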

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

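The tests without the 2 libraries of highest mitochondrial share and without the 7 libraries between others and the splits within days and of whole groups were chosen after the data were seen. The difference between doses changed from day to day for 234 genes in an F-test of the interaction (3192 below 0.05 before adjustment), and these genes are set out here because their dose effect differs between days. The immediate early genes Arc (adjusted p = 0.000985) and Junb (0.0139) had a dose effect that differed between days, largest at day 7. Arc stood at 12.0, 52.9 and 52.6 FPKM from the lowest to the highest dose at day 7 (1/2 minus 1/10 LD50 on the log2 scale 2.07 ± 0.22, SE), with differences of 0.43 ± 0.22 at day 1, 0.36 ± 0.22 at day 3 and 0.01 ± 0.22 at day 14. Junb stood at 6.73, 17.7 and 18.0 FPKM at day 7 (1.34 ± 0.18). Of the chaperones, Pdia4 (adjusted p = 0.00376) was higher at 1/2 than at 1/10 LD50 at day 1 (0.38 ± 0.10) and lower at day 7 (-0.58 ± 0.10), and Calr (0.00538) likewise (0.36 ± 0.06 and -0.21 ± 0.06). Hacd1, a fatty acid dehydratase (0.00538), differed by 0.69 ± 0.10 at day 7 and by -0.30 ± 0.10 at day 14, and Tnfrsf25, a receptor of the tumor necrosis factor family (0.00538), stood at 0.854, 3.26 and 1.97 FPKM at day 7 (0.67 ± 0.14). Rpl30 (3.79e-06), whose copies make its level uncertain, stood at 121.7, 115.8 and 8.32 FPKM at day 1 (-3.73 ± 0.31).

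The count of 234 was 1120 without replicate 1 of every group, 7 without replicate 2 and 1 without replicate 3. It was 43 without the 2 libraries of highest mitochondrial share, both of 1/10 LD50 at day 7, and 1 without the 7 libraries between the others of their group. Without the 2 the adjusted p was 0.0501 for Arc, 0.0035 for Pdia4, 0.00556 for Calr, 0.00953 for Hacd1, 0.0375 for Tnfrsf25 and 1.12e-05 for Rpl30. Without the 7 it was 0.214 for Arc, Pdia4, Calr and Tnfrsf25, 0.076 for Hacd1 and 0.0156 for Rpl30. The interaction of Junb was not retested without the 2 or without the 7, though its difference at day 7 rests on the same 1/10 LD50 group. Of 100 splits of libraries over the doses of their own day 1, the real one, gave as many as 234 genes (highest other 146). With doses of whole groups exchanged within each day, 87 of 100 arrangements did (highest other 1006). Such an exchange keeps the differences between the groups of a day, so high counts are likely whatever their source, and it cannot measure chance. The splits of libraries part those of a group, which resemble each other, so chance is not excluded. Splits that mixed days (highest other 57) say nothing, as they could not give a high count. No explanation of this difference was tested.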

How the results depend on the processing

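The tests with the length trend removed, without the 2 libraries of highest mitochondrial share and without the 7 libraries between others were chosen after the data were seen. Of 132 values of 18 results under alternatives that leave out no library singly, 84 were within 1.5 times the reported one, and 48 were not. The balance of rises and falls turned for 6 results: with only the groups compared more rose than fell at 1/5 (177 and 173) and 1/2 (527 and 453) at day 3, 1/10 (3 and 2) and 1/5 (1462 and 1370) at day 7, 1/5 at day 14 (41 and 30) and day 14 against day 1 (1471 and 1455). It also turned at 1/5 at day 14 with no filter (8 and 7) and without own replicate 3 (3 and 0). For day 14 against day 1 it turned with median-ratio scaling (1420 and 1137), without the 7 libraries (352 and 333), and without replicate 3 of 1/10 (976 and 973) or 1 of 1/2 at day 1 (954 and 910) or replicate 2 of 1/10 (1112 and 974) or 1 or 2 of 1/2 at day 14 (939 and 916, 959 and 951). The cause of the changes was not tested, except that leaving out libraries leaves fewer samples. Groups are given by dose and day. A pseudocount of 0.1 moved no count beyond 1.5 times.

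With no filter on low values, limma called 0 at 1/5 LD50 at day 1 (2449 below 0.05 before adjustment), 15 at 1/5 at day 14 and 59 for the interaction. Median-ratio scaling gave 93 at 1/10 and 4 at 1/5 at day 1 and 52 at 1/5 at day 14. With only the groups compared in the model, counts were 122, 27 and 30 at day 1 from the lowest to the highest dose, 214 and 350 at 1/10 and 1/5 at day 3, 5 and 556 at 1/10 and 1/2 at day 7, 71 and 32 at 1/5 and 1/2 at day 14, 89 for the interaction and 0 for all soman (pooled as 1 group, 1184 below 0.05 before adjustment). The estimated correlation left 20 of 191 list calls, and gave 10 to 21 calls when any 1 of the 39 libraries was left out. With the length trend removed, counts were 90 at 1/10 at day 1, 461, 589 and 549 at day 3, 938 and 537 at 1/5 and 1/2 at day 7, 47 at 1/5 at day 14, 85 for all soman and 2 for 1/2 against 1/10 LD50.

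Without the 2 libraries of highest mitochondrial share, counts were 4 at 1/10 at day 7, where the 1 library left is assumed to vary like the other groups, 671 for all soman, 2 for 1/2 against 1/10 LD50 and 43 for the interaction. Without the 7 libraries they were 9, 0 and 1 at day 1 (406 below 0.05 before adjustment at 1/5), 144, 203 and 140 at day 3, 69, 756 and 196 at day 7, 0, 0 and 0 at day 14 (1186, 646 and 965 before adjustment), 1 for all soman, 2 for 1/2 against 1/10 LD50, 685 for day 14 against day 1, 4409 for any day and 1 for the interaction.

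Leaving out 1 replicate gave 129 values, of which 76 were beyond 1.5 times the reported count and 66 of these lower. At day 1 counts ranged over 28 to 58, 0 to 6 and 3 to 13 from the lowest to the highest dose, at day 3 over 349 to 989, 453 to 1626 and 297 to 965, at day 7 over 668 to 5304, 1131 to 1764 and 277 to 1437, and at day 14 over 9 to 38, 0 to 13 and 10 to 34. They ranged over 0 to 45 for all soman, 3 to 2555 for 1/2 against 1/10 LD50, 1748 to 2086 for day 14 against day 1, 3693 to 5441 for any day, 1 to 1120 for the interaction and 191 to 205 for list calls. The 0 counts, with 682, 612, 1117, 1185 and 1564 genes below 0.05 before adjustment in limma, came without saline replicate 3 or own replicate 3 (1/5 at day 1), without saline replicate 3 or own replicate 2 (1/5 at day 14) and without replicate 3 of every group (all soman).

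With the replicate number as a block, counts moved by at most 1.5 times (4 for 1/2 against 1/10 LD50, 59 at 1/10 at day 1, 321 for all soman, 172 for the interaction, 2139 for day 14 against day 1, 192 list calls), and the samples share only a number: same-numbered libraries had a mean correlation of deviations of -0.003 (-0.326 to 0.355), and 14 of 39 were closest to their own number. Depth is unknown, so what it limits could not be measured.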

Other observations

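The tests of transcript length alone and of a batch shared by a day for days 3 and 7, the mixture test for the 7 libraries and the splits of whole groups were chosen after the result was seen. Between day 14 and day 1, some genes of vessel walls and of glia fell besides the haemoglobin genes, though none of their lists passed there with an estimated correlation. Kdr, the main receptor for VEGF on endothelium, fell from 6.34 ± 0.918 to 4.13 ± 0.301 FPKM (SD, n = 9 each; log2 change -0.51 ± 0.06, SE, limma adjusted p = 4.08e-07, 9 of 9 libraries below all of day 1), and Vwf, a clotting factor carrier, by 0.57 ± 0.08. They are among 5 of 17 endothelial genes that fell, while 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.747 with an estimated correlation). Pdgfrb, a receptor of pericytes, fell by 0.44 ± 0.05, among 3 of 12 genes of pericytes and smooth muscle (4 adjusted over the list alone, where 1 rose, adjusted p = 0.346 with an estimated correlation). Genes of oligodendrocyte progenitors fell in 6 of 13 (8 adjusted over the list alone, adjusted p = 0.155 with an estimated correlation), among them Pdgfra, their growth factor receptor (9.76 ± 0.774 to 7.66 ± 0.517 FPKM, -0.31 ± 0.05). Those of microglia fell in 9 of 22 (12 adjusted over the list alone, adjusted p = 0.568 with an estimated correlation), among them P2ry12, a receptor for nucleotides (-0.43 ± 0.09).

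Glucocorticoid response genes rose in 10 of 17 between day 14 and day 1 (12 rose and 1 fell adjusted over the list alone, adjusted p = 0.125 with an estimated correlation). Among them Errfi1, an inhibitor of EGF receptors, rose by 0.31 ± 0.04 on the log2 scale in 9 of 9 libraries and Pdk4, a kinase that restrains glucose oxidation, by 0.39 ± 0.07 in 8 of 9. Of 18 circadian clock genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.346 with an estimated correlation), and Per1, a clock repressor, went from 13.6 ± 1.92 to 21.3 ± 2.80 FPKM (0.61 ± 0.07, adjusted p = 1.25e-06, 8 of 9 libraries above all of day 1). The hour of sampling is not in the labels. Chat rose by 0.30 ± 0.10 (adjusted p = 0.0365), a call lost without any of 12 of the 18 libraries (up to 0.0824) and without the 7 (0.162).

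More genes differed from saline at days 3 and 7 than at days 1 and 14, together with a trend on transcript length. A length trend as the whole cause is argued against, as at least 461 genes still passed at each dose of day 3 with it removed against 90 at most at day 1, and 565 against 128 with trends on length and GC content removed. A batch shared by the libraries of a day cannot be told apart from a change with time, since day and collection coincide. Between 1/2 and 1/10 LD50 limma called 0 genes at day 3 (778 below 0.05 before adjustment), and 2597 at day 7 but 6 without the 2 libraries of highest mitochondrial share, though 1 library of 1/10 LD50 is then left. An effect of soman at these days stays open and untested for want of saline of the same days.

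Meningeal fibroblast markers were lower in the mean of the soman groups, though not at 1/2 LD50 at day 1 (2.776 ± 0.034 against 2.773 ± 0.105 in saline). A length trend is argued against, as the median log2 change was -0.4011 with it removed and -0.3876 before. So is a single saline library, as the median was -0.3073 without saline replicate 1, -0.4322 without 2 and -0.4103 without 3. Different amounts of meningeal tissue in the samples stay open: within groups the members' mean correlation was 0.199, above the 95th percentile of 1000 random lists (0.127) though not their highest (0.224), and choroid plexus markers were lower in 12 comparisons at the preset correlation, in none with an estimated one. A change in the meninges after soman stays open as well.

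In 7 libraries, 6 of them numbered 3, values lay between those of the other 2 of their group. A chance figure of 1.05 of 39 holds only if libraries of other groups are as likely to lie there. As groups differ, libraries of the same group may lie nearer each other, so that figure cannot measure chance here. The shares rest on 40 to 66 genes in the 6 numbered 3, and on 495 in the library numbered 2. A mixture of material from the other 2 libraries would place all genes near their mean, and the ratio of variance in 5 of the 7 (0.172 to 0.331) was below that of all 32 others (lowest 0.393), while the other 2 (0.413 and 0.623) lay among them, with 6 of the 32 below 0.623. As the 7 were chosen for lying between, the ratio partly restates that choice, and a mixture stays open. A gradient of RNA quality along length and GC content is argued against, as 7 of 7 were still nearer the middle than every outside library with these trends removed. If they are mixtures, spreads within groups are too small and p values too low, which is why counts without the 7 are given, and no biological explanation was tested.

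Other splits of the same libraries into groups of the same sizes were run for each count. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and in each of the 12 comparisons 1 split, the real one, gave as many genes. From the lowest to the highest dose, the real counts and the highest of the other splits were 51 and 0, 2 and 0, and 17 and 0 at day 1; 1025 and 0, 1265 and 1, and 1241 and 1 at day 3. They were 2866 and 1843, 2258 and 0, and 1234 and 0 at day 7, and 64 and 0, 24 and 1, and 61 and 1 at day 14. The split with 1843 genes took replicate 1 of 1/10 LD50 at day 7 as saline and so left the 2 libraries of highest mitochondrial share together.

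The 100 splits of single libraries part libraries of a group, which resemble each other, and so give low counts. They gave 1 as large for day 14 against day 1 (2197 against 856 at most) and 1 for any day (7277 against 183). With whole groups moved, 1 of 100 arrangements of the days, the real one, gave as many as 7277 (highest other 7122, median of the others 3028). That share is under 0.05, by a narrow margin in the count. It cannot tell a change with time from a batch shared by the libraries of a day. For day 14 against day 1 there are 10 such arrangements, too few for a share under 0.05, and 1 gave as many as 2197 (highest other 156). For all soman against saline 3 splits gave as many as the real 378. The highest other split gave 3020 genes and took the 2 libraries of highest mitochondrial share as saline, which points to a structure of the samples, and with whole groups set in turn against the other 12, 7 of 13 gave as many (highest other 4802). Saline as a group therefore does not stand out, and chance is not excluded there. Chance is not excluded for 1/2 against 1/10 LD50 (8, 6 genes against 910 at most) or for the list calls at the preset correlation (27, 191 against 267 at most). The split with 910 genes set the 2 libraries of highest mitochondrial share in opposite doses, and what raised its count was not tested. For the calls with an estimated correlation 1 split of libraries gave as many (20 against 9 at most), but with whole groups moved 6 of 100 did (highest other 21), so chance is not excluded there either.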
